A study of Mus musculus with 6 samples.

How the data were processed

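Gene expression was measured in primary prostate cells of p53-null mice whose Rb gene carries loxP sites. Per the labels, cultures were infected overnight with an adenovirus carrying lacZ, which leaves Rb intact, or with an adenovirus carrying Cre recombinase, which deletes Rb. RNA was taken 48 hours after infection. Each group had 3 samples, and the series design speaks of independent experiments. Cy3-labelled RNA of each sample was hybridised to its own array, so all 6 arrays were of 1 colour.

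The scanner files hold intensity values, made by the authors with Agilent Feature Extraction, version 11.0.1.1 per the file headers; the submitters' processing notes name version 10.7.3.1. Per the file headers, the processed intensity is the spot brightness after background subtraction, with no scaling between arrays. The deposited files also carry flags, valued 0 or 1, for spots well above background, saturated spots and outlying spots. The authors deposited in addition a table of log2 values, whose scale and centring no label gives. Each of its columns equalled the log2 processed intensity of that sample's array minus a constant, within 0.01 for 100% of its probes. Its column medians lay between -0.52 and -0.49, and its direction is that of the intensity. It held 22164 non-control probes.

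From the scanner files, the 43020 non-control spots per array were used, without those marked as outlying, and spots of the same probe were averaged to 39429 probes. The log2 processed intensity of each array was shifted by its 75th percentile. A probe was kept if it was well above background on all 3 arrays of at least 1 group, which 23051 probes were. Probes were named by matching their RefSeq accession, without version, to a gene table of assembly GRCm38.p6. This matched 27427 probes to 20832 genes, and 12002 probes stayed unnamed. The array was designed on build mm9 per the file headers, so the table served only for names and for which genes neighbour each other, and no coordinates are given. Each gene was represented by its passing probe with the highest mean over the 6 arrays, which gave 13731 tested genes.

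The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no block, Benjamini-Hochberg adjusted p under 0.05). Levels are log2 intensity relative to the array's 75th percentile, given as mean ± SD with n = 3. Differences are Rb deleted minus Rb intact on the log2 scale, given ± SE of the fit. Where a group was not well above background on any of its arrays, the fold is a lower bound. The bright group's mean was then set against the dim group's mean of, on each array, the higher of the probe's own signal and the lowest signal among probes well above background. In the text, rose and fell mean an adjusted p under 0.05.

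Gene lists were tested with camera in limma at a preset inter-gene correlation of 0.01, adjusted over the 22 lists. Camera with an estimated correlation and fry were run beside it. The test, the lists, the rule for named genes and most other settings were chosen before the data were examined. The rule named Rb1 and Trp53, the 10 largest rises and the 10 largest falls among changed genes whose groups did not overlap and whose symbol is a gene name, and up to 4 measured members per list with the smallest p. For lists of cell type markers it added the member with the highest mean signal. Some genes that the rule names are not reported here. Other genes named in the text were chosen after their values were seen.

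Other settings tried, fixed at the same time, covered scaling, the filter on dim probes, the choice of probe, the variance model, array weights, slide, replicate number, thresholds, the deposited log2 values and leaving out each array. A background model on mean spot signal was not run, because the deposited intensity columns used here are processed and median signals; the same model on median signal, with an offset of 50, was added after the files were seen.

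The limma fit, without the scaling, filter and probe choice before it, was tested on simulated data made from the 13731 genes, in 5 runs with 200 changed genes each. It recovered 54.5% of genes changed by 0.5, 83.1% of those changed by 1 and 96.4% of those changed by 2 on the log2 scale, and 5.22% of its calls were false. The simulated genes varied independently, with no slide effect or outlying array. Far fewer of them changed than the 2804 called in the real data, so the share of false calls need not hold there. The number of arrays limits the precision of every value.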

Results

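The data were expression profiles of 6 primary prostate cell cultures that lacked p53, 3 with Rb intact and 3 with Rb deleted. The series was made to develop gene sets that follow the loss of Rb, the retinoblastoma protein that restrains entry into S phase, where p53 is already absent. Between 59.0% and 63.3% of probes were well above background on each array, and no spot was saturated. Pearson's r over probes, which are not independent replicates, was 0.993 to 0.998 within a group and 0.987 to 0.992 between groups. Spike-in transcripts lay at -4.13 ± 0.17 relative to the 75th percentile in Rb intact and -4.11 ± 0.07 in Rb deleted (SD, n = 3 each; exact two-sided permutation p = 0.8).

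The arrays lay on 2 slides. The first slide held all Rb intact arrays and Rb deleted 1, and the second held Rb deleted 2 and 3, so only the first slide compares the groups. Vector and Rb status went together in every culture, since Rb intact cells had the lacZ virus and Rb deleted cells the Cre virus. The first principal component, with 59.0% of the variance, separated the groups. On the second, with 22.3%, Rb intact 1 scored 22.96 and Rb intact 2 and 3 scored -15.32 and -14.52.

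The targeted gene was lower in every Rb deleted culture. Rb1, measured by probe A_51_P136888, stood at -1.14 ± 0.02 in Rb intact and -3.10 ± 0.03 in Rb deleted (SD, n = 3 each). Rb1 fell by 1.96 ± 0.05 (SE), to 25.8% of the intact signal, with a limma adjusted p of 8.39e-05. The exact two-sided permutation p was 0.1, the smallest that 3 against 3 arrays can give. Within the first slide, whose only Rb deleted array was taken to vary like the Rb intact arrays, the Rb1 difference was -1.97 (limma adjusted p = 0.0221). The second slide holds no Rb intact array, so the fit with slide as a block rests on the same contrast and gave the same -1.97 (adjusted p = 0.00545). The position of the probe relative to the deleted part of the gene was not known here, so the fall describes this probe's transcript region. Trp53, the tumour suppressor gene inactivated in all 6 cultures, was well above background on all 6 arrays, at -2.44 ± 0.28 in Rb intact and -2.75 ± 0.13 in Rb deleted (SD, n = 3 each), a difference of -0.31 ± 0.15 (SE, limma adjusted p = 0.202). The position of its probe relative to the inactivated part of the gene was not known here either, so this signal does not check the labels.

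The comparison of Rb deleted with Rb intact cells asked which transcripts differ 48 hours after the virus. Among lists of genes, 31 of 55 for DNA replication, 25 of 55 for mitosis, 15 of 38 for recombination and checkpoints and 17 of 38 of the interferon response rose, and 11 of 19 squamous differentiation genes fell. The chemokine gene Ccl5 rose 3.37-fold, and the envelope protein gene Ivl (4.58-fold) and the smooth muscle actin gene Acta2 (2.55-fold) fell. Of 13731 genes, 1326 rose and 1478 fell, 2804 in all or 20.4% of those tested. When every probe was tested on its own, 366 of 618 changed genes with several passing probes had a probe not past the threshold. For 1 gene, Ahnak, a probe was called in the opposite direction. Changes were small for most genes, with a median size of 0.42 on the log2 scale among those changed. Counting bounds in place of fitted values, 62 rose and 187 fell by at least 2-fold. The groups did not overlap for 6205 genes, or 45.2%, against 10% by chance. With slide as a block, 208 genes rose and 469 fell, and within the first slide 30 rose and 124 fell. Leaving out Rb intact 1 gave 5102 changed genes; leaving out Rb intact 2 or 3 gave 1743 and 1691, and leaving out Rb deleted 1, 2 or 3 gave 1780, 1241 and 1256.

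**Figure D1:**
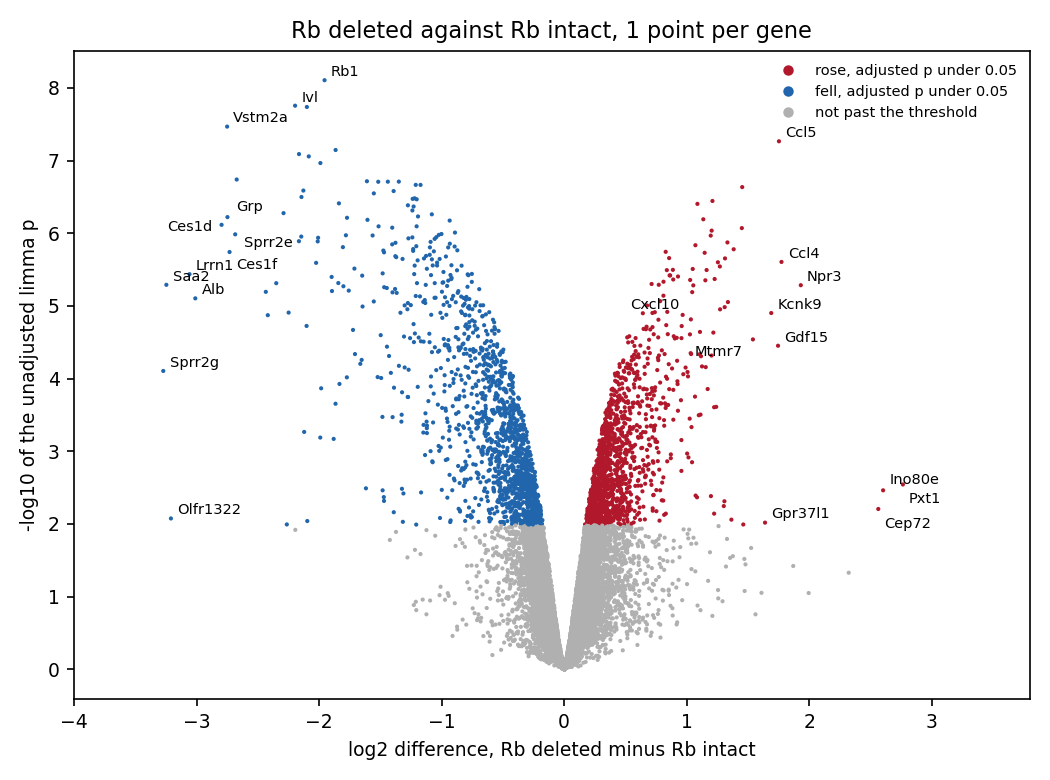
Each point is a gene, with the log2 difference (Rb deleted minus Rb intact, n = 3 each) on the horizontal axis and -log10 of the unadjusted limma p on the vertical axis; red genes rose, blue genes fell and grey genes did not pass an adjusted p of 0.05. Rb1 at -1.96 and Ivl at -2.20 are among the highest points on the left and Ccl5 at 1.75 on the right; genes below background in a group, such as Sprr2g, Saa2 and Cep72, are drawn at fitted values that give no fold.

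Among the largest rises with signal in both groups were Npr3, the clearance receptor for natriuretic peptides, at 1.93 ± 0.14 (3.81-fold, limma adjusted p = 0.000498), and the chemokines Ccl4 at 1.77 ± 0.11 (3.42-fold) and Ccl5 at 1.75 ± 0.06 (3.37-fold, adjusted p = 0.000149). Gdf15, a stress-induced cytokine of the TGF-beta family, rose by 1.75 ± 0.17 (3.35-fold), Mtmr7, a myotubularin-related phosphatase, by 1.54 ± 0.14 (2.91-fold), and the potassium channel gene Kcnk9 by 1.69 ± 0.14, with 1 of 3 Rb intact arrays well above background. Pxt1 rose by 2.76 ± 0.58 (adjusted p = 0.0221) and Gpr37l1, an orphan receptor gene, by 1.64 ± 0.45 (adjusted p = 0.0479). Ino80e, a chromatin remodelling subunit, and Cep72, a centrosome component, were not well above background in any Rb intact array and were at least 1.89-fold and at least 2.39-fold higher (adjusted p = 0.0249 and 0.0366). The calls of Pxt1, Gpr37l1, Ino80e and Cep72 were each lost with slide as a block, without Rb intact 2 or 3, and without at least 1 Rb deleted array; that of Gpr37l1 was lost also without Rb intact 1.

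The largest falls with signal in both groups were Vstm2a at -2.75 ± 0.09 (6.73-fold, limma adjusted p = 0.000117), Grp, which encodes gastrin-releasing peptide, at -2.75 ± 0.14 (6.72-fold), the carboxylesterase Ces1f at -2.73 ± 0.16 with 2 of 3 Rb deleted arrays above background, and Sprr2e, a cornified envelope precursor, at -2.68 ± 0.15 (6.43-fold). Several genes were not well above background in any Rb deleted array and so have only bounds. These were Sprr2g (at least 5.94-fold lower, adjusted p = 0.00243), albumin or Alb (at least 4.35-fold, adjusted p = 0.000632), Lrrn1 (at least 4.12-fold, adjusted p = 0.000435), Olfr1322 (at least 3.82-fold, adjusted p = 0.0443), the acute phase gene Saa2 (at least 2.86-fold, adjusted p = 0.000497) and Ces1d (at least 2.24-fold, adjusted p = 0.00027). The Olfr1322 call was lost without Rb intact 2 and without each Rb deleted array in turn. Sprr, Saa and Ces1 genes have paralogs, and whether these share probe signal was not tested, so their single values are uncertain.

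DNA replication and G1/S genes rose together. Of 55 measured members 31 rose and none fell, and 41 rose when adjusted over the list alone; the median difference was 0.31. Cdt1, which loads the replicative helicase, rose by 0.46 ± 0.05 (1.38-fold, limma adjusted p = 0.00271), and Cdc45, part of the active helicase, by 0.52 ± 0.06 (1.43-fold). The mismatch repair gene Msh6 rose by 0.44 ± 0.05 and Lig1, the ligase that joins Okazaki fragments, by 0.40 ± 0.05. Camera gave an adjusted p of 2.25e-12, and 0.0168 with an estimated correlation.

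Mitosis and G2/M genes also rose, 25 of 55 with no fall, and 38 adjusted over the list alone, with a median of 0.28. Cdc25b, a phosphatase that activates Cdk1, rose by 0.62 ± 0.06 (1.54-fold, limma adjusted p = 0.00157), its relative Cdc25c by 0.45 ± 0.05, the chromosomal passenger gene Cdca8 by 0.45 ± 0.05, and the spindle kinase gene Aurka by 0.42 ± 0.05. Camera gave an adjusted p of 7.99e-11, against an adjusted p of 0.0735 with an estimated correlation. Of 38 homologous recombination and replication checkpoint genes, 15 rose and none fell, 17 adjusted over the list alone, and the median was 0.26. Topbp1, an activator of the ATR kinase, rose by 0.38 ± 0.05, Rad54b by 0.48 ± 0.06, the end-resection gene Rbbp8 by 0.37 ± 0.06 and the helicase gene Blm, whose call was lost without Rb deleted 3, by 0.38 ± 0.06. Camera gave an adjusted p of 4.53e-07, against an adjusted p of 0.0697 with an estimated correlation.

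Within the first slide, and with slide as a block, the medians of these proliferation lists were 0.30 for replication, 0.31 for mitosis and 0.24 for recombination. With the block 3, 3 and 0 members rose, and within that slide no member passed limma's threshold, although 1952 of all genes had an unadjusted p under 0.05 there. Without Rb intact 1, 45, 43 and 25 members rose; without Rb deleted 3, 17, 7 and 3 did, and without Rb deleted 2, 15, 8 and 4. Camera at the preset correlation also put the replication list past the threshold in 8 of the other 9 ways to split the 6 arrays into 3 and 3, the mitosis list in 7 and the recombination list in 7. Each of those splits mixes the groups unequally, so part of the real difference stays in it. These counts therefore do not show how often chance alone would put a list past the threshold.

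**Figure D2:**
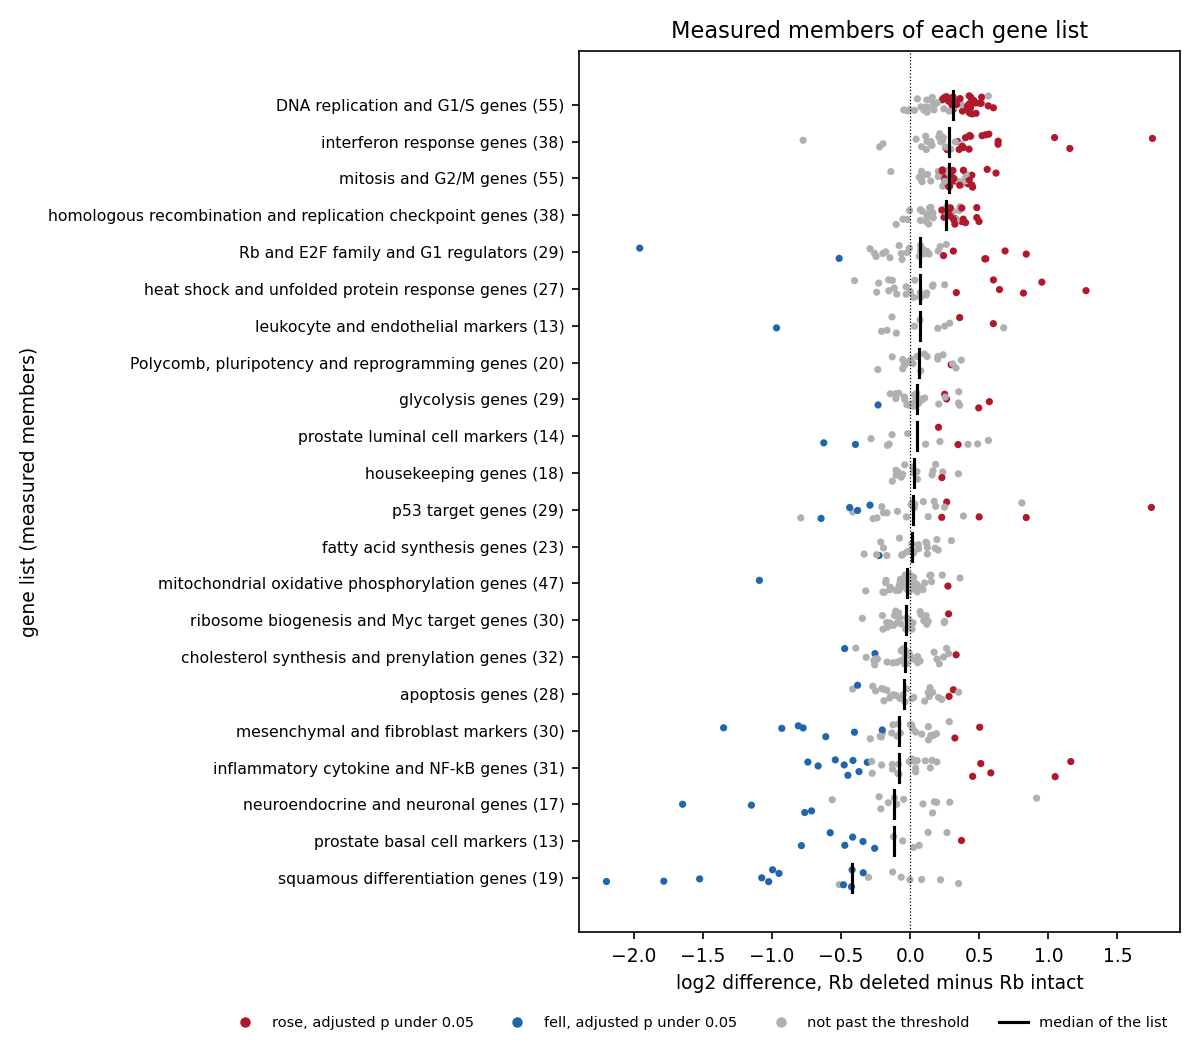
Each point is a measured member of a gene list, placed by its log2 difference (Rb deleted minus Rb intact, n = 3 each); red members rose, blue members fell, grey members did not pass an adjusted p of 0.05, and black bars are list medians. The replication, interferon, mitosis and recombination lists sit to the right with medians of 0.31, 0.28, 0.28 and 0.26, and the squamous list to the left with a median of -0.42.

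Of 29 measured members of the Rb and E2F family and its G1 regulators, 6 rose and 2 fell, and 8 and 4 did adjusted over the list alone. The list was not set apart from other genes by camera (adjusted p = 0.705), while fry gave an adjusted p of 0.0178, upward. Both tests included Rb1, the targeted gene, whose fall works against an upward shift, and neither was run without Rb1. The Cdk inhibitor gene Cdkn1a rose by 0.84 ± 0.10 (1.79-fold, limma adjusted p = 0.00274) and Mybl2, a cell cycle transcription factor, by 0.54 ± 0.10, while Cdkn1c, another Cdk inhibitor gene, fell by 0.51 ± 0.07; Rb1 was the other fall. The Mybl2 call was lost when any 1 Rb deleted array was left out. Among 29 p53 target genes, 5 rose and 4 fell, 6 and 7 adjusted over the list alone (camera adjusted p = 0.908). Gdf15 and Cdkn1a were the largest rises there, Ddit4, an inhibitor of mTOR signalling, rose by 0.50 ± 0.07, and Perp, a desmosome gene, fell by 0.64 ± 0.09. Of 28 apoptosis genes 2 rose and 1 fell, with the same numbers adjusted over the list alone (camera adjusted p = 0.761). The caspase gene Casp2 rose by 0.31 ± 0.05 and the death receptor gene Fas fell by 0.38 ± 0.07. The Casp2 call was lost without Rb deleted 2 or 3. Of 20 Polycomb, pluripotency and reprogramming genes only Myc rose, by 0.30 ± 0.08 (limma adjusted p = 0.0446), and none did adjusted over the list alone (camera adjusted p = 0.507). Myc was past the threshold when Rb intact 1 was left out, and not when any other array was. With slide as a block 1 Rb and E2F family member rose and 1 fell and 2 p53 targets rose, with no other call in these lists, and within the first slide the only call was the fall of Rb1.

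Interferon response genes rose in 17 of 38 measured members with no fall, and in 19 adjusted over the list alone, with a median of 0.28. Besides Ccl5, the chemokine gene Cxcl10 rose by 1.05 ± 0.08 (2.06-fold, limma adjusted p = 0.000565), Oas3, which senses double-stranded RNA, by 1.16 ± 0.13 (2.23-fold), and Ifih1, the cytoplasmic RNA sensor MDA5, by 0.52 ± 0.06. Camera gave an adjusted p of 7.05e-08, against an adjusted p of 0.351 with an estimated correlation. Within the first slide, and with slide as a block, the median was 0.27; 5 members rose with the block, 1 within that slide, 25 without Rb intact 1 and 8 without Rb deleted 2. Rb intact 1 itself lay above the other Rb intact arrays on this list by a median of 0.12. The list was past camera's threshold in 6 of the other 9 splits, which keep part of the real difference and do not measure chance.

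Inflammatory cytokine and NF-kB genes moved both ways, 5 of 31 up and 8 down, and 6 and 9 adjusted over the list alone (camera adjusted p = 0.563). Tslp, an epithelial alarmin, rose by 1.16 ± 0.08 (2.24-fold, limma adjusted p = 0.000408), and the IL-6 family cytokine genes Il11 and Lif rose by 1.05 ± 0.07 and 0.58 ± 0.06, while the acute phase gene Saa3 fell by 0.67 ± 0.07. Of 27 heat shock and unfolded protein response genes 6 rose and none fell, also 6 adjusted over the list alone (camera adjusted p = 0.279; fry adjusted p = 0.0016, upward). They included Atf3 (1.27 ± 0.10, 2.42-fold), Trib3 (0.95 ± 0.12), Ddit3 (0.82 ± 0.08) and Asns (0.60 ± 0.08), all known targets of the stress transcription factor Atf4. Without Rb intact 1, 9 of the 27 heat shock and unfolded protein response genes rose and 4 fell. In the fit with slide as a block 2 of these genes rose, Atf3 and Ddit3, and 3 inflammatory genes rose and 1 fell; within the first slide none of the 27 passed limma's threshold, and 2 inflammatory genes, Tslp and Il11, rose.

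Squamous differentiation genes fell in 11 of 19 measured members with none up; adjusted over the list alone 12 fell and 1 rose. The median was -0.42. Ivl, which encodes the cornified envelope protein involucrin, fell by 2.20 ± 0.06 (4.58-fold, limma adjusted p = 8.39e-05), and S100a8, a calcium-binding alarmin, fell by 1.78 ± 0.10 (3.44-fold). Crct1 fell by 1.07 ± 0.07, Sprr1a fell by 1.02 ± 0.06, and the brightest member, the cystatin gene Cst6, fell by 0.99 ± 0.08. Camera gave an adjusted p of 1.97e-06, against an adjusted p of 0.123 with an estimated correlation. Within the first slide, and with slide as a block, the median was -0.39; 7 members fell with the block and 4 within that slide. Without Rb intact 1, 13 fell and 1 rose. The list was past camera's threshold in 3 of the other 9 splits, which keep part of the real difference and do not measure chance.

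**Figure D3:**
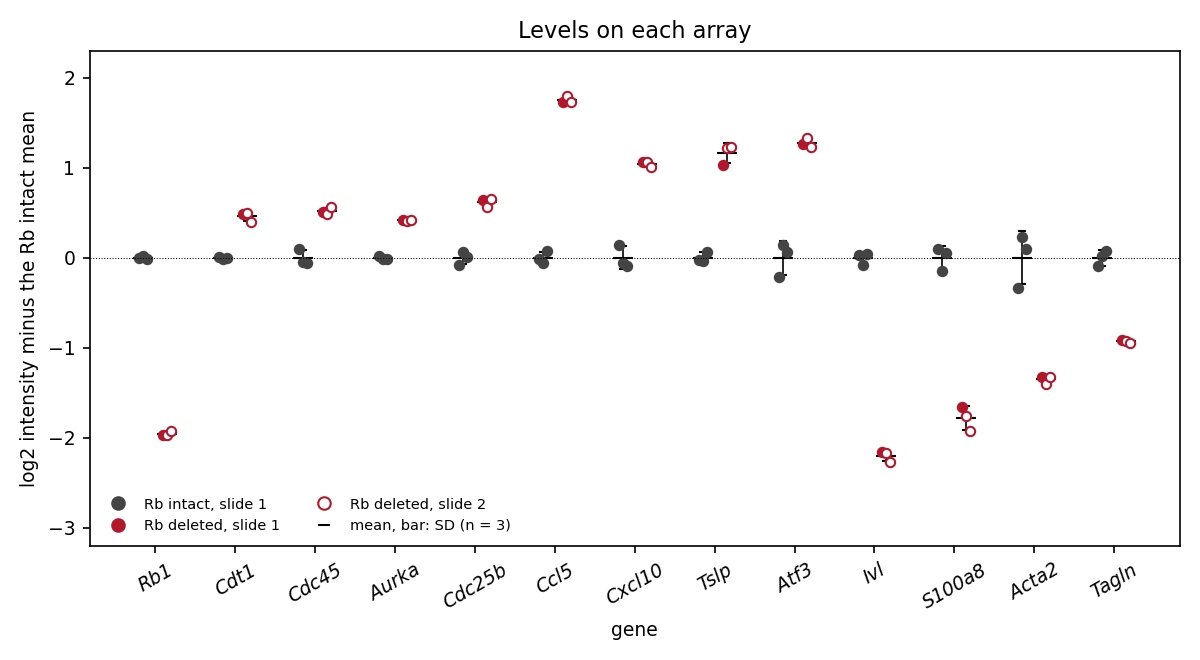
Points are single arrays for 13 genes, as log2 intensity minus that gene's Rb intact mean, grey for Rb intact and red for Rb deleted, with open points for the second slide; bars mark each group's mean and SD (n = 3). Rb deleted 1, on the slide of the Rb intact arrays, lies with Rb deleted 2 and 3 for each gene drawn, from Ivl at -2.20 to Ccl5 at 1.75. All genes drawn had small p values, which favour arrays that agree within a group, so this does not test for a slide difference.

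Markers of cell types that the culture could hold included genes that fell. Of 13 prostate basal cell markers 6 fell and 1 rose, and 6 and 2 did adjusted over the list alone. Against other genes camera gave an adjusted p of 0.127, or 0.0286 with the mean of each gene's probes, and fry, which asks whether members move on balance in 1 direction, gave an adjusted p of 0.00108, downward. The aquaporin gene Aqp3 fell by 0.79 ± 0.07, the laminin receptor gene Itga6 fell by 0.58 ± 0.08 and the linker gene Dst fell by 0.34 ± 0.06, while the Notch ligand gene Jag1 rose by 0.37 ± 0.06. Of 14 luminal markers 2 rose and 2 fell, and 4 and 2 did adjusted over the list alone (camera adjusted p = 0.705). Nupr1 rose by 0.35 ± 0.06 and Fkbp5, an androgen-responsive gene, by 0.21 ± 0.05, while clusterin or Clu fell by 0.62 ± 0.11 and Cldn3, a tight junction gene, fell by 0.40 ± 0.07. The brightest, Ly6a, gave -0.02 ± 0.15 (limma adjusted p = 0.944). Without Rb deleted 2 the calls of Dst, Jag1, Nupr1 and Fkbp5 were lost, and without Rb deleted 3 those of Jag1, Nupr1, Fkbp5 and Cldn3; Cldn3 and Fkbp5 lost theirs also without Rb deleted 1 or Rb intact 2, and Fkbp5 without Rb intact 3. With slide as a block 1 basal marker, Aqp3, fell and no luminal marker passed limma's threshold, and within the first slide no member of either list did. Of 17 neuroendocrine and neuronal genes 4 fell and none rose, also 4 adjusted over the list alone. Camera gave an adjusted p of 0.202, or 0.0472 without Rb intact 1, and fry an adjusted p of 0.00304, downward. Stmn2, a microtubule regulator, was at least 2.95-fold lower (adjusted p = 0.000714), Peg10 fell by 0.76 ± 0.11 and Uchl1 fell by 0.71 ± 0.09, while the brightest, Ncam1, gave 0.16 ± 0.12 (adjusted p = 0.392). Only Stmn2 of the neuroendocrine genes passed limma's threshold with slide as a block and within the first slide.

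Of 30 mesenchymal and fibroblast markers 7 fell and 2 rose, the same numbers adjusted over the list alone (camera adjusted p = 0.127; fry adjusted p = 0.00208, downward). The smooth muscle actin gene Acta2 fell by 1.35 ± 0.14 (2.55-fold, limma adjusted p = 0.00222), and the contractile genes Tagln (-0.93 ± 0.06) and Cnn1 (-0.81 ± 0.07) fell. S100a4 fell by 0.77 ± 0.06, and the brightest, Sparc, gave -0.09 ± 0.09 (limma adjusted p = 0.511). Without Rb intact 1, 6 of the 30 mesenchymal markers rose and 10 fell. Of 13 leukocyte and endothelial markers Cd14 (0.36 ± 0.06) and the VEGF receptor gene Flt1 (0.60 ± 0.12) rose and Vwf (-0.97 ± 0.18), with 1 of 3 Rb deleted arrays well above background, fell, as they did adjusted over the list alone (camera adjusted p = 0.563); the brightest, Itgam, gave -0.17 ± 0.46 (adjusted p = 0.819). Cd14 and Flt1 lost their calls without Rb deleted 2 or 3, Cd14 also without Rb intact 2, and Flt1 also without Rb deleted 1 or Rb intact 3. With slide as a block 5 mesenchymal markers and 1 leukocyte or endothelial marker fell and none rose; within the first slide no mesenchymal marker passed limma's threshold, and 1 leukocyte or endothelial marker fell.

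Metabolic and housekeeping lists did not pass camera's threshold. Of 29 glycolysis genes 4 rose and 1 fell, 2 and 1 adjusted over the list alone (adjusted p = 0.149; fry adjusted p = 0.0092, upward), with the lactate exporter gene Slc16a3 up by 0.57 ± 0.06, Vegfa by 0.50 ± 0.09 and Pdk1 by 0.26 ± 0.07, and Ldhb down at -0.23 ± 0.05. Among 32 cholesterol synthesis and prenylation genes Pmvk rose by 0.33 ± 0.06 and Hsd17b7 (-0.47 ± 0.07) and Acat2 (-0.25 ± 0.07) fell; adjusted over the list alone 1 rose and 1 fell (adjusted p = 0.507; fry adjusted p = 0.00663, downward). Dgat2, which makes triglyceride, fell by 0.22 ± 0.06 as the only change among 23 fatty acid synthesis genes, and none changed adjusted over the list alone (adjusted p = 0.952); that list's median was 0.012, while its mean of -0.002 and its test pointed down. Among 47 mitochondrial oxidative phosphorylation genes, Tfam, a mitochondrial DNA packaging factor, rose by 0.27 ± 0.06 and Ppargc1a, a coactivator of mitochondrial genes, was at least 1.84-fold lower (limma adjusted p = 0.0113); 1 fell and none rose adjusted over the list alone (camera adjusted p = 0.705). Odc1 of 30 ribosome biogenesis and Myc target genes rose by 0.28 ± 0.07 (camera adjusted p = 0.908), and Tfrc of 18 housekeeping genes by 0.23 ± 0.06 (camera adjusted p = 0.705); adjusted over the list alone neither did. Calls of Ldhb, Pdk1, Dgat2, Odc1 and Tfrc were lost when any array but Rb intact 1 was left out; those of Vegfa and Pmvk were lost without Rb deleted 2 or 3, of Acat2 and Tfam also without Rb intact 2 or 3, and of Ppargc1a without Rb deleted 2. With slide as a block the only call in these lists was the rise of Slc16a3, and within the first slide limma gave none.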

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

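Tests were chosen for this part after the result was seen, apart from the statement about the vector, which follows from the design. Some values come from settings that were planned, namely fry, the fit on the first slide alone and the fits that leave out an array. Counts of list members taken from these fits were added after the data were seen. Of 12002 probes that matched no gene in the table used here, 5101 passed the filter on dim probes and were tested, and 235 of these rose and 411 fell in Rb deleted cells (limma adjusted p under 0.05); they drew attention because the comparisons of named genes leave them out.

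Rb intact 1 stood apart from Rb intact 2 and 3, with 22.96 on the second principal component against -15.32 and -14.52. A culture with Rb deleted under the wrong label is argued against by Rb1, which lay 1.95 log2 units above the Rb deleted mean; an exchange with a sample outside the series was not tested. A weak hybridisation stays open, since the 75th percentile of the processed signal was lower on Rb intact 1, 3514 against 4149 and 3874; the share of probes well above background, 62.0% against 59.2% and 59.3%, was the first criterion and excluded it, but the signal was added after the values were seen, because the lowest signal counted as above background was lower too, -6.36 against -6.02 and -5.98 on the log2 scale. Rb deleted 2 had a floor of -6.54 and a 75th percentile of 3769. It still differed least from the other arrays of its group, with an SD of the difference over genes of 0.16, against 0.34 for Rb intact 1. A low floor alone thus need not set an array apart, but the signal of Rb intact 1 was lower still. Another mix of cells stays open. The cell type list that differed most, the squamous genes, gave a median of -0.15 ± 0.09 (SE over members), against a bound of 0.25 in size. Within 2 SE the squamous list reaches past that bound. So do the neuroendocrine list, at -0.03 ± 0.14, and the leukocyte and endothelial list, at -0.006 ± 0.135, so none of these 3 lists excludes it. The design names no biological difference among the Rb intact cultures, so none was tested beyond that mix of cells; without this array 5102 genes changed in place of 2804.

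Interferon response genes were higher in Rb deleted cells, by a median of 0.28. A difference between the slides is argued against by the median within the first slide, 0.27. More leukocytes in the Rb deleted cultures stay open: 7 of 17 leukocyte markers were measured, with a median of 0.20, between the level that would count for leukocytes and the level that would count against them, and 8 of 17, among them Ptprc, Cd68, Lyz2 and Tyrobp, were not well above background on any Rb deleted array. The vector cannot be told apart from Rb status, since in 0 of the groups did the vector and Rb status part. A response to the Cre virus may therefore account for the rise as well as the deletion of Rb could.

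Squamous differentiation genes were lower in Rb deleted cells, by a median of -0.42. The median within the first slide, -0.39, argues against a difference between the slides as the whole cause, and signal shared between paralogs is argued against by 6 fallen members outside the Sprr, Lce, S100a, Krt, Klk and Dsg families, namely Crct1, Cst6, Evpl, Ivl, Lor and Sbsn. A lower share of epithelial cells stays open: the basal list had a median of -0.12, above the squamous median by 0.30, which is less than the SD of 0.34 over its members. That SD is the spread among genes and not the error of a median, so this comparison does not decide the question. Of 13 basal markers 6 fell and 1 rose. Against a lower share stands the luminal list, at 0.05 and above the squamous median by 0.47 with an SD of 0.35, though the squamous members' own SD was 0.69. The mesenchymal list, which a lower share would raise, also stands against it, at -0.08 with 7 of 30 fallen and 2 risen (fry adjusted p = 0.00208, downward). A first criterion on the mesenchymal and basal medians excluded a lower share. That criterion was replaced after its values were seen, since bright mesenchymal markers would hide a small rise. Without Rb intact 1, 6 mesenchymal markers rose and 10 fell, so the mesenchymal counts depend on that array. The deletion of Rb and the different vector are both possible explanations that this design does not separate.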

How the results depend on the processing

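Alternatives here were planned, except the background model on median spot signal and the member counts of lists without Rb intact 1 and within the first slide, which were added after seeing the data. Rb1 kept its direction and its call under each alternative run, between -1.97 and -1.74. The count of changed genes, 2804, became 1485 with no filter on dim probes, 6856 with array weights, 677 with slide as a fixed block, 154 on the first slide alone and 264 with a 2-fold minimum on fitted values. Leaving out 1 array gave 1241 to 5102. The share of rises, 47.3%, was 30.7% with the slide block, 19.5% on the first slide and 36.5% without Rb deleted 2. Fewer residual degrees of freedom are part of the slide and leave-one-out counts by construction, while for the other settings the cause was not tested. Slide as a random block gave 4093 genes and the deposited log2 values 2778. The estimated correlation within slides was -0.204, which treats arrays of 1 slide as less alike than arrays of different slides. The 4093 genes therefore do not show that allowing for slide strengthens the result.

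No pairing by replicate number was visible, since same-numbered arrays deviated from their group means with correlations of -0.033, -0.057 and 0.015, and not every array correlated best with its own number. Whether equal numbers mark the same experiment stays open. The arrays numbered 2 and 3 lay on different slides in each group, so a slide difference could hide a pairing. The replicate block gave 1642 genes and changed no call of a list or of Rb1.

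Of 22 lists, 5 passed camera at the preset correlation, 1 with an estimated correlation and 12 with fry, which does not compare a list with other genes. The count was 6 with the mean of a gene's probes, which added basal markers (0.0286), and 6 without Rb intact 1, which added neuroendocrine genes (0.0472). Camera with an estimated correlation did not call mitosis (0.0735), recombination (0.0697), squamous (0.123) and interferon genes (0.351). The estimate was above the preset 0.01 for mitosis (0.0449), squamous (0.0721) and interferon genes (0.219), so the preset may be too low for these lists. For recombination it was 0.0118, near the preset, and for replication -0.0098, yet the camera adjusted p of replication still rose to 0.0168. The size of the correlation thus did not by itself end the recombination call or raise the replication value, and the cause was not tested. The forms of camera therefore differ in more than the correlation. How much of the change for mitosis, squamous and interferon genes came from their correlation was not separated. Of 110 named genes other than Rb1, 88 passed the threshold. Over all alternatives their call was unchanged 1846 times, lost 270 times and gained 57 times, and 1 value reversed. Of the losses 71 were on the first slide alone and 46 with the slide block. Ly6a, at -0.02, ranged from -0.13 to 0.16 when 1 array was left out, and reversed without Rb intact 1; the cause was not tested. Probes near background limit the dimmest genes to bounds.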

Other observations

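The tests in this part were chosen after the results were seen, apart from the counts of splits. The genes of this part were named after their values were seen.

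Posterior genes of the HoxD cluster, which pattern the distal body axis and the urogenital tract, rose, and 9 of 25 other measured Hox genes fell. Hoxd12 rose by 1.45 ± 0.06, Hoxd10 by 1.34 ± 0.10, Hoxd11 by 1.31 ± 0.10, Hoxd13 by 0.75 ± 0.16 and Hoxd9 by 0.36 ± 0.06 (limma, n = 3 per group), so 5 of 5 measured members from Hoxd9 to Hoxd13 rose. None of the other Hox genes rose, and those that fell included Hoxd4 (-0.74 ± 0.07), Hoxc6 (-0.82 ± 0.08) and Hoxb9 (-1.31 ± 0.29). As a hypothesis, the posterior end of HoxD may change apart from the other Hox genes. Fisher's exact test of direction against position among called Hox genes gave a two-sided p of 0.0004995, but it ran on genes picked because they showed the pattern, and neighbouring genes are not independent, so it does not decide the hypothesis.

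Changes gathered in some runs of neighbours in the gene order of assembly GRCm38.p6. In windows of 10 adjacent tested genes, ranked by mean limma t and set against 1000 permutations of gene order, the lowest mean t spanned Sprr2e, Sprr1a, Ivl and Lce1g, with 9 of 10 genes down and a median of -0.99 (permutation p = 0.001, the smallest they can give). A window of stefin genes, cysteine protease inhibitors such as Stfa2 and Csta2, had 8 of 10 down and a median of -1.13 (permutation p = 0.001, also the smallest), and a window of S100a genes ending at Lor had 6 of 10 down (permutation p = 0.035). Among rises, the window holding HoxD had 5 of 10 up (permutation p = 0.005) and the window holding Npr3 and Rad1 had 6 of 10 up (permutation p = 0.017). These were 5 of the 12 windows listed, the 6 highest and the 6 lowest that do not overlap. The other 7 did not pass 0.05, among them windows of Gbp genes (permutation p = 0.0599) and Phf11 genes (0.0799) up and of Lce genes (7 of 10 down, 0.513) and Ces1 genes (3 of 10 down, 0.696). By family, 7 of 8 Sprr, 7 of 9 Lce, 6 of 8 stefin, 3 of 3 Ces1 and 3 of 4 Serpinb9 genes fell, while 7 of 15 H3 and H4 histone genes rose and none fell, and of 23 H2a and H2b histone genes 5 rose and 7 fell. Whether paralogs in these families share probe signal was not tested, so the numbers of genes are uncertain.

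The cultures carried strong mesenchymal signal. Vim, Sparc, Col1a1, Col1a2, Col3a1 and S100a4 were well above background on all 6 arrays, as were Krt14, Krt8, Krt18, Krt19 and Trp63, whereas Epcam and Cdh1 were on none. Of the lists, 30 of 32 mesenchymal, 13 of 26 basal and 14 of 31 luminal markers were measured.

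Other splits of the 6 arrays into 3 and 3 number 10 with the real one, too few for a share under 0.05. The real split gave 2804 changed genes and the highest other split 0, so 1 of 10 gave as many. For gene lists the real split gave 5 past camera's threshold and the highest other split 7, reached by Rb intact 1 and Rb deleted 1 with either Rb deleted 2 or Rb deleted 3, and 3 of 10 gave at least as many as the real one. Every other split mixes the groups unequally. Part of the real difference therefore stays in its contrast and the rest adds to the spread, so neither count shows what chance alone would give. The ribosome biogenesis and Myc target list, with a camera adjusted p of 0.908 in the real split, passed in 4 of the other 9 (smallest camera adjusted p = 0.00175). A call at the preset correlation in a mixed split thus need not come from a difference between the groups.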
